A study of Chlamydomonas reinhardtii with 25 samples.

How the data were processed

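RNA was sequenced from 25 samples of Chlamydomonas reinhardtii strain CC-125, 5 in each of the groups control, Ce, Tm, Y and Mix. Per the labels' protocols, cells grown at 20 °C under 12 h of light per day were exposed for 2 h in 10 mM NaHEPES at pH 7.0 with 10 µM calcium nitrate. Polyadenylated RNA was selected, stranded libraries were prepared, and paired reads of 100 bases were sequenced on 2 lanes. The labels do not say which library ran on which lane, nor on which day a sample was exposed, so no batch could be entered in a model.

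The deposited table holds whole-number read counts per annotated transcript, not normalised, with 1 column per library and a gene ID for each of its 19526 transcripts. Per the submitters' processing notes, Trim Galore 0.3.7, TopHat2 2.0.14 and SAMtools 1.2 were used. The program that counted the reads, its use of strand, the genome build and the annotation release are not given in the sources used here. Reads from overlapping or antisense genes and from near-identical copies can therefore not be told apart, and no coordinates are printed. Columns were matched to samples by name and each sample's group was taken from its title. Totals per library ran from about 12921000 to 28974000 counts, and every column was used.

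In 34 cells, each in a different transcript, the text "PAC:" stood before or inside the number, in front of digits with which the transcript numbers of the table begin. No intact cell (0) held these digits, and the 34 cells were read as the number without that text. Leaving out the 34 transcripts was tried as an alternative. In that fit edgeR took control library 1 as the TMM reference in place of Tm library 2, so it was repeated with Tm library 2 kept as the reference. A further 1502 gene IDs stood on 2 lines each (3004 lines). Of these lines 72.0% were at 0 in all libraries, against 3.15% of the others, and they held 0.110% of all counts. They were kept as deposited, and summing them per ID was an alternative. No 2 libraries of a group were alike to within sampling noise: the lowest chi-square per degree of freedom of any pair within a group was 5.97.

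The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust estimates, TMM scaling, low counts removed by filterByExpr by group), with all 25 libraries in 1 fit and a coefficient per group. It tested 12796 transcripts with 12790 distinct IDs. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called. Standard errors of log2 fold changes were derived from the same fit, as the absolute change divided by the square root of the F statistic. CPM were taken relative to the TMM-scaled library total, and log2 CPM used a prior count of 2. The comparisons were each exposure against the control, Ce against Tm, Ce against Y, Tm against Y, Mix against the mean of the 3 metals and against the sum of their effects, the mean of the metals against the control, and any difference between the 5 groups. Groups, comparisons, tests, the rule for named genes and most alternatives were fixed before the data were examined. Mix against each single metal was added afterwards.

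The scripts were tested on simulated counts with 200 changed genes. For Ce against control 98.0% of 50 genes with a 4-fold change and 72.0% of 50 with a 2-fold change were recovered among 12454 genes, and 4.35% of the calls were false. For Mix against control these values were 96.0%, 64.0% and 5.88% among 12457 genes. The simulated groups all had the same spread and few genes changed, while in the data the controls spread most and most genes were called. The simulation thus tests the code and does not give the share of false calls in these data.

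Named genes were to be taken from those with an adjusted p under 0.05, a mean of at least 1 CPM and all 5 libraries of the first group on the same side of the mean of the second, ordered by fold change. Where neither the table nor the reference names genes, the rule allows at most 2 IDs that rose and 2 that fell per comparison, and this limit applied. The reference used here (assembly Chlamydomonas_reinhardtii_v5.5) gives locus tags in place of symbols: 11194 of the 12464 IDs of the Cre form matched a locus tag, and 0 symbols other than locus tags were found. The 27 gene lists fixed for this organism and treatment therefore matched 0 members and could not be tested, so none of their results exists here. The reference served only to find which genes are neighbours.

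The groups share replicate numbers 1 to 5, and whether these numbers pair the samples was checked by correlating deviations from the group means across genes between libraries of the same number. All 5 correlations were over 0.1 for Ce with Y (0.111 to 0.188) and for Tm with Mix (0.193 to 0.440), and each of these libraries correlated best with its own number. In these comparisons the numbers were taken to pair the samples, a pairing that comes from the data and not from the labels. The other pairs of groups did not meet this rule. Ce with Tm missed it narrowly (0.0826 to 0.226), and each Ce library correlated best with the Tm library of its own number. The main test did not enter the numbers, so its counts, standard errors and p-values for Ce against Y and Mix against Tm are unpaired. With the replicate number as a block, 9772 genes were called for Ce against Y and 288 for Mix against Tm, in place of 9435 and 150.

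Alternatives were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter and a stricter filter, only the groups compared, the replicate number as a block, stricter thresholds, each library left out in turn, and 1 surrogate variable (sva 3.50.0). Added after the data had been seen were library totals without scaling factors, voom with a spread per group, the damaged transcripts left out, counts summed per ID, controls 1 and 4 left out together, all libraries thinned to about 12921000 counts, each of the 25 libraries as the TMM reference, genes of the mixture comparison chosen with each exposure left out in turn or by all 4, and these genes by the count that the sum of effects predicts. For values shared between exposures, all 25 libraries were simulated 20 times as unchanged, from the means and dispersions of the controls. Each gene was drawn independently. The real controls were also divided into 2 and 3 libraries in 20 ways. Differences of a single value between groups were tested by two-sided exact permutation tests, with sign flips of pairs for Ce against Y.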

Results

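Transcript abundance was measured by RNA sequencing in Chlamydomonas reinhardtii, a unicellular green alga, using the wild-type strain CC-125. Cells taken in mid-exponential growth were held for 2 h in a buffered medium at pH 7.0 with cerium (Ce), a light rare earth element, thulium (Tm), a heavy one, or yttrium (Y), which is usually grouped with the heavy elements. The concentration was 0.5 µM, and a further group received an equimolar mixture of the 3 metals (Mix). Each of these 4 exposures and the control was represented by 5 libraries, 25 in all. Total counts per library ran from about 12921000 in Tm library 2 to about 28974000 in control library 2. Of 19526 annotated transcripts, called genes here, 12796 had enough counts to be tested. Genes are given by the IDs of the deposited table, which pairs them with no names, and no function can be attached to them here. Levels are CPM, the usual unit of counts relative to the scaled library total, as mean ± SD over 5 libraries, and changes are log2 fold changes with their standard errors (SE). P-values measure the spread between these libraries, since the labels do not say whether the replicates were separate cultures.

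Nearly every tested gene differed between some of the 5 groups. The test over all groups called 12292 of the 12796 genes (96.1%). The first 2 principal components held 42.9% and 38.5% of the variance. The controls lay apart from all exposed libraries on the first, and the Ce libraries lay apart from Tm, Y and Mix on the second. Group means of log2 CPM correlated across genes at r = 0.996 between Tm and Mix, 0.990 between Tm and Y and 0.984 between Y and Mix, against 0.923, 0.931 and 0.921 between Ce and Tm, Y and Mix, and 0.880 to 0.924 between the controls and the exposures (genes are not independent replicates). The coefficient of biological variation was 32.1% in the controls, 17.2% in Mix, 13.1% in Tm, 10.6% in Ce and 9.95% in Y, so the libraries of the control group spread most.

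**Figure D1:**
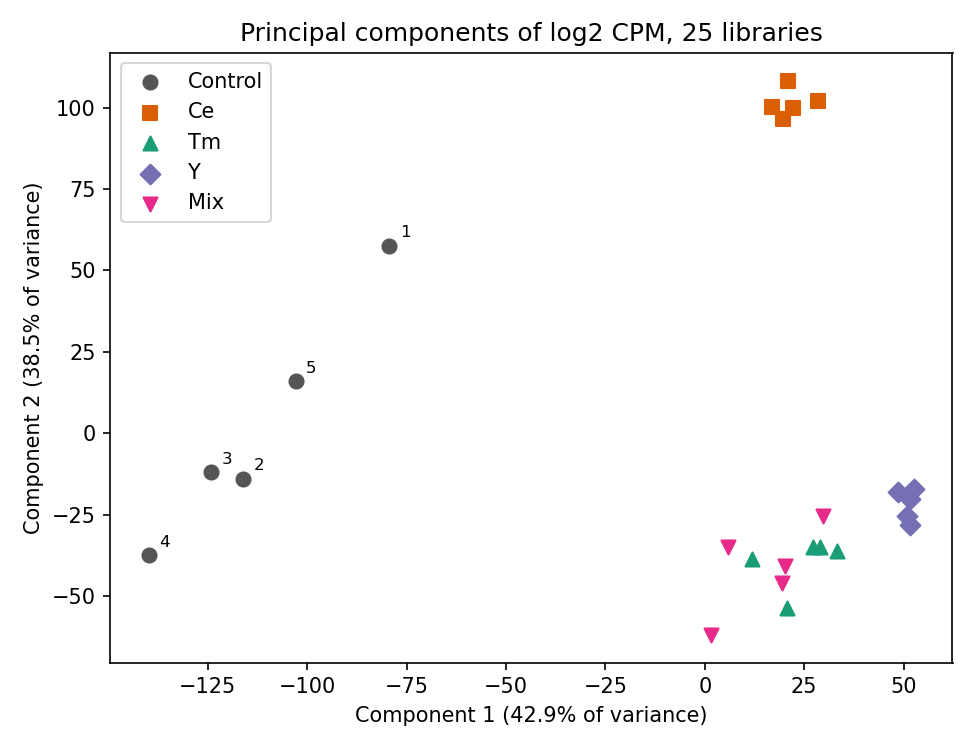
Principal components of log2 CPM over the 12796 tested genes, with 1 point per library, colour and shape for the group, and numbers for the 5 control libraries. The axes give scores on component 1 (42.9% of the variance) and component 2 (38.5%); Ce forms a cluster of its own, Tm, Y and Mix lie together, and the controls are spread along component 2 from -37.5 (control 4) to 57.6 (control 1).

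Of the 4 exposures, Ce differed from the control in the most genes. Of the 12796 genes, 5741 were higher and 4635 lower than in the control, 3848 and 2918 of them by at least 2-fold. The ID with the largest rise was Cre10g448150, from 0.470 ± 0.244 CPM in the control to 17.8 ± 3.04 in Ce (log2 fold change 5.27 ± 0.26, edgeR quasi-likelihood test, adjusted p = 5.1e-16). It was followed by Cre16g6922001, from 0.139 ± 0.101 to 5.74 ± 1.91 CPM (5.15 ± 0.36, adjusted p = 4.88e-13 by the same edgeR test). The largest fall was that of Cre13g603550, from 188 ± 81.2 to 0.720 ± 0.252 CPM (-7.98 ± 0.43, adjusted p = 3.94e-15, edgeR). Cre01g044450 fell from 7.54 ± 3.31 to 0.0607 ± 0.0647 CPM (-6.82 ± 0.42, adjusted p = 4.29e-14, edgeR), where the Ce level rests on 9 counts in 5 libraries. The scaling factors of the Ce libraries (1.43 ± 0.03, against 0.86 ± 0.18 in the controls) set the balance of rises and falls. With library totals alone the median change of all genes moved from 0.22 to 0.95, and 75.1% of the calls were rises in place of 55.3%.

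In Tm, 4114 genes were higher and 4824 lower than in the control, 2113 and 3277 of them by at least 2-fold. Cre12g556700 rose from 0.0710 ± 0.0625 to 6.24 ± 1.51 CPM (log2 fold change 6.40 ± 0.37, edgeR adjusted p = 8.56e-15), with 6 counts in all in the 5 control libraries. Cre17g697750 rose from 0.666 ± 0.431 to 29.4 ± 3.04 CPM (5.43 ± 0.26, edgeR adjusted p = 1.46e-16). The largest falls were those of Cre08g363600, from 17.5 ± 9.51 to 0.301 ± 0.162 CPM (-5.82 ± 0.39, edgeR adjusted p = 1.65e-13), and g16214, from 36.4 ± 23.9 to 0.849 ± 0.367 CPM (-5.46 ± 0.46, edgeR adjusted p = 1.71e-11). The share of rises, 46.0% of the calls, ran from 41.2% to 54.9% when each of the 25 libraries in turn served as the scaling reference, so the order of rises and falls depends on that choice.

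In Y, 4593 genes were higher and 4699 lower than in the control, 2727 and 3279 of them by at least 2-fold. Cre12g556700, the ID that led the rises in Tm, also led them in Y, where it reached 12.1 ± 1.01 CPM (log2 fold change 7.35 ± 0.36, edgeR adjusted p = 1.09e-16). Cre03g185750 rose from 0.223 ± 0.144 to 19.1 ± 2.47 CPM (6.43 ± 0.26, edgeR adjusted p = 2.21e-18). Cre13g603550, the leading fall in Ce, was the leading fall in Y as well, at 1.41 ± 0.48 CPM (-7.05 ± 0.42, edgeR adjusted p = 5.9e-15). Cre10g463400 fell from 17.8 ± 5.82 to 0.233 ± 0.103 CPM (-6.19 ± 0.34, edgeR adjusted p = 1.13e-15). The share of rises was 49.4%, and 44.5% to 53.6% over the 25 scaling references.

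In Mix, 3951 genes were higher and 4803 lower than in the control, 1997 and 3223 of them by at least 2-fold. The largest rises were those of the IDs that led in Tm. Cre17g697750 reached 31.0 ± 5.89 CPM (log2 fold change 5.50 ± 0.26, edgeR adjusted p = 1.38e-16) and Cre12g556700 reached 2.93 ± 1.00 CPM (5.30 ± 0.40, edgeR adjusted p = 1.63e-12). Cre01g044450 fell to 0.217 ± 0.065 CPM (-5.07 ± 0.38, edgeR adjusted p = 1.68e-12) and Cre07g320400 fell from 11.5 ± 3.66 to 0.364 ± 0.133 CPM (-4.94 ± 0.27, edgeR adjusted p = 2.05e-15). The share of rises was 45.1% with the scaling reference that edgeR chose, Tm library 2, and it ran from 40.9% to 56.3% (control library 1) over the 25 references. The number of calls stayed between 8709 and 8850 over those references.

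**Figure D2:**
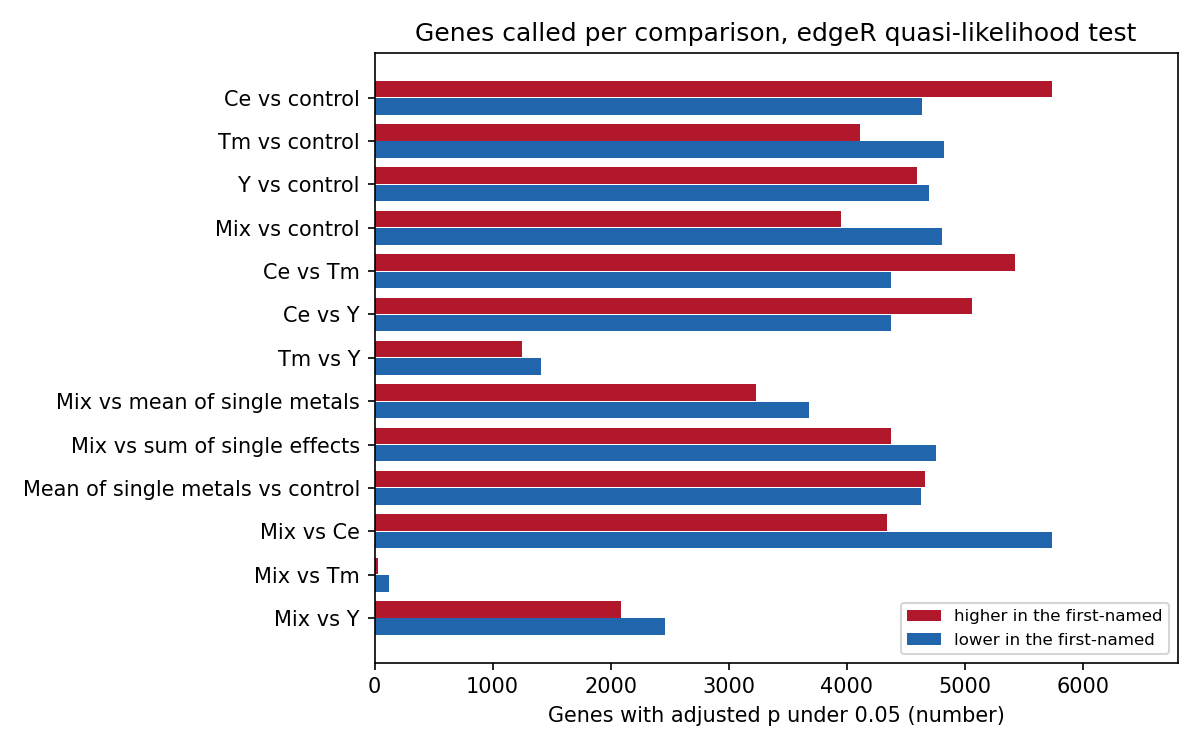
Number of genes with an adjusted p under 0.05 in each comparison (edgeR quasi-likelihood test, 12796 genes tested), higher (red) and lower (blue) in the group named first; the bars have no error bars because each is a count. Comparisons with the control and with Ce hold 3951 or more calls in each direction, and Mix against Tm holds 25 higher and 125 lower.

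The mean of the 3 single-metal groups was also set against the control, with 4660 rises and 4631 falls. A change in a single metal can suffice for a call on the mean, so these counts do not give the genes common to the metals. Cre03g185750 (log2 fold change 5.46 ± 0.25) and Cre12g524200, from 1.24 ± 0.63 CPM in the control to 37.3 ± 5.86 in Ce, 42.0 ± 5.14 in Tm and 84.3 ± 9.20 in Y (5.30 ± 0.20), rose most, with edgeR adjusted p = 9.13e-18 and 3.03e-19. Cre13g603550 (-6.70 ± 0.25) and Cre01g044450 (-5.91 ± 0.27) fell most, with edgeR adjusted p = 3.03e-19 and 1.34e-17. Taken metal by metal, in groups formed after the data had been seen, 2540 genes were called higher in Ce, Tm and Y, and 2854 were called lower in all 3. Of the first group, Mix was also called higher in 2284 genes and lower in 1. Of the second, Mix was called lower in 2727 and higher in 0 by edgeR, with the remaining 127 not called in Mix. With library totals alone, the common group of rises grew to 3516 and that of falls shrank to 2058, and the share of rises in the mean of the metals was 63.7% in place of 50.2%.

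**Figure D3:**
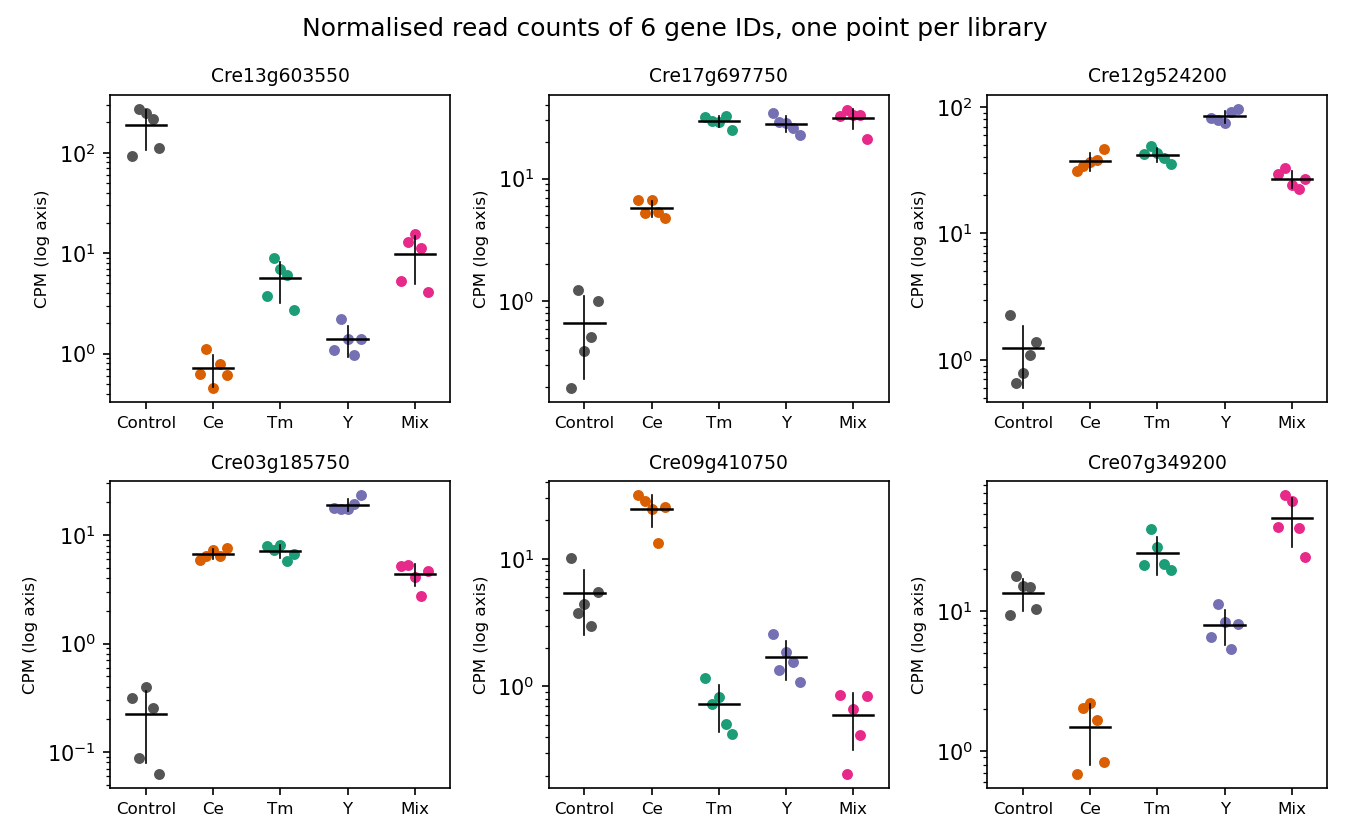
CPM on a log axis for 6 gene IDs, with 1 point per library, a horizontal line at the mean and a vertical line for ± 1 SD (n = 5 per group). Cre13g603550 is at 188 CPM in the control and under 10 CPM in every exposure mean, Cre12g524200 and Cre03g185750 are higher in all exposures, and Cre09g410750 and Cre07g349200 move in opposite directions in Ce and Mix.

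The exposures shared many calls. Tm and Mix shared 8114 calls in the same direction and had 5 in opposite directions. Tm and Y shared 7972 with 13 opposite, and Y and Mix 7563 with 51 opposite. Ce shared 5538 calls with Tm, 6295 with Y and 5277 with Mix, and had 1738, 1315 and 1831 in opposite directions. Independent lists of these sizes would share 3081 calls for Tm and Mix, 3248 for Tm and Y, 3182 for Y and Mix, and 3593, 3763 and 3512 for Ce with Tm, Y and Mix. In 20 simulations of unchanged groups, with the controls simulated too, 0 calls were shared on average by edgeR. Each gene was drawn independently there, while the main axis of the real controls held 69.2% of their variance. The simulations therefore do not show what these control libraries add to the shared calls or to r. The log2 fold changes correlated across genes at r = 0.97 (Tm and Mix), 0.95 (Tm and Y) and 0.92 (Y and Mix). For Ce with Tm, Y and Mix r was 0.57, 0.67 and 0.55. The simulations, where only the simulated controls are shared, gave 0.50 to 0.52. The covariances were 1.68, 1.98 and 1.83, and 1.18, 1.58 and 1.07 for Ce, against 0.08 in the simulations. With the controls split so that each exposure had its own, the mean r over 20 splits was 0.88, 0.87 and 0.84, and 0.54, 0.64 and 0.51 for Ce, whose values depended on the controls used (0.25 to 0.73 with Tm, 0.40 to 0.78 with Y and 0.21 to 0.72 with Mix).

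Set against Tm directly, Ce libraries had 5422 genes higher and 4374 lower, and against Y 5062 higher and 4373 lower. In 4488 genes Ce lay above both Tm and Y, with median log2 fold changes against control of 1.02 in Ce, -0.71 in Tm, -0.49 in Y and -0.70 in Mix. In 3773 genes Ce lay below both, with medians of -0.62 in Ce, 0.49 in Tm, 0.44 in Y and 0.50 in Mix. Among these, 638 genes were called higher than the control in Ce and lower in both Tm and Y, and 494 the reverse. Cre16g6678501 was at 5.32 ± 2.14 CPM in Ce, 0.0995 ± 0.0957 in Tm and 0.0852 ± 0.0597 in Y (log2 differences of 5.71 ± 0.53 and 5.84 ± 0.53, edgeR adjusted p = 2.82e-10 and 2.12e-10). Cre06g285050 was at 4.66 ± 0.54 CPM in Ce, 0.0815 ± 0.0667 in Tm and 0.0839 ± 0.0856 in Y (5.70 ± 0.55 and 5.65 ± 0.53, edgeR adjusted p = 5.16e-10 and 4.55e-10). Both rest on 7 or 8 counts in all in the Tm and in the Y libraries. Cre12g556700 was at 0.214 ± 0.103 CPM in Ce (31 counts in all) and 0.0710 ± 0.0625 in the control (6 counts). It was lower in Ce than in Tm and Y (-4.87 ± 0.28 and -5.82 ± 0.28, edgeR adjusted p = 1.4e-13 and 4.25e-15). Cre15g643050 fell to 0.0639 ± 0.0564 CPM in Ce, against 1.55 ± 0.36 in Tm and 1.86 ± 0.45 in Y (-4.43 ± 0.43 and -4.69 ± 0.42, edgeR adjusted p = 6.39e-10 and 1.92e-10). With library totals alone, 76.1% of the calls against Tm and 75.4% of those against Y were higher in Ce, in place of 55.3% and 53.7%, with 6927 genes above both and 2011 below both, and 954 and 133 genes moved in opposite directions in place of 638 and 494. With control library 1 as the scaling reference the balance turned, to 48.2% and 49.2%, with 3906 above both and 4239 below both, and 468 and 779 genes moved in opposite directions.

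The direction of the difference between Ce and Tm followed transcript abundance. Among the least abundant 3199 tested genes, 1622 were at least 2-fold higher and 348 at least 2-fold lower in Ce. Among the most abundant 3199, 109 were higher and 1011 lower. The median log2 difference went from 1.05 in the least abundant genes through 0.75 and 0.11 to -0.68 in the most abundant. With library totals alone, 11.1% of the most abundant genes were at least 2-fold higher and 7.16% at least 2-fold lower in Ce, in place of 3.41% and 31.6%, so the fall of abundant transcripts depends on the scaling.

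**Figure D4:**
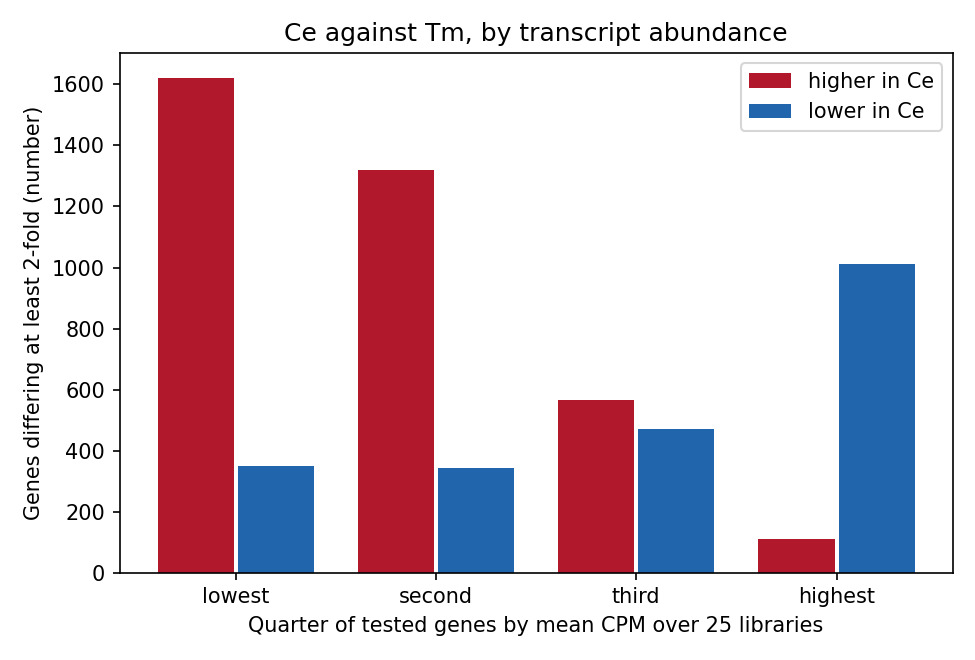
Number of genes at least 2-fold higher (red) or lower (blue) in Ce than in Tm with an adjusted p under 0.05, for 4 equal parts of the tested genes ordered by mean CPM over the 25 libraries; the bars are counts and have no error bars. Rises number 1622 in the least abundant part and 109 in the most abundant, falls 348 and 1011.

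Tm and Y gave similar profiles. Between them 94.9% of the genes lay within 2-fold, and 1247 genes were higher and 1412 lower in Tm. Cre06g294150 was at 7.06 ± 4.97 CPM in Tm and 1.22 ± 0.44 in Y (log2 difference 2.54 ± 0.46, edgeR adjusted p = 0.000317), and g15585 at 67.6 ± 31.5 and 13.4 ± 5.03 CPM (2.34 ± 0.30, edgeR adjusted p = 6.74e-06). Both were higher in the control than in either metal, at 24.9 ± 7.24 CPM for Cre06g294150. In every group library 5 had the highest CPM of both IDs. For Cre06g294150 in Tm it had 15.4 CPM, against 3.15 to 7.56 in the other Tm libraries. Lower in Tm were g16307, at 1.15 ± 0.51 against 5.72 ± 1.48 CPM (-2.26 ± 0.26, edgeR adjusted p = 2.07e-06), and Cre17g702950, at 1.99 ± 0.92 against 8.67 ± 2.27 CPM (-2.12 ± 0.28, edgeR adjusted p = 7.74e-06). The share of genes higher in Tm, 46.9%, was 59.9% with upper-quartile factors and 70.4% with control library 1 as the scaling reference, so no direction of the bulk can be read from it. The number of calls was 4536 when the fit held only these groups and 4621 with a spread estimated per group.

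The series title names interactions between the elements as its subject, and the mixture was therefore set against the single metals in 2 ways, because the labels do not say whether 0.5 µM is the total or the level of each metal. Against the mean of the single metals, Mix was higher in 3228 genes and lower in 3676, of which 306 and 905 differed by at least 2-fold. Mix differed from Tm in 150 genes and from Ce in 10079. A call against the mean can therefore come from the distance of Ce alone and need not be an interaction. Genes called in the same direction in Ce, Tm, Y and Mix, a choice made after the data had been seen so that no exposure is favoured, numbered 2284 higher and 2727 lower. The median log2 fold change of the first was 1.30 in Ce, 1.29 in Tm, 1.58 in Y and 1.19 in Mix, and Mix lay nearer the control than the metals' mean in 860 genes and farther from it in 333. Those of the second were -1.75, -1.61, -1.89 and -1.57, with 996 nearer the control and 223 farther. Tm set against the mean of the other 3 in the same genes was nearer the control in 329 and farther in 363 of the rises, and nearer in 660 and farther in 135 of the falls. Ce was nearer in 895 and farther in 679 of the rises, and nearer in 855 and farther in 1003 of the falls. Y, with the largest response, was nearer in 50 and farther in 1121 of the rises and nearer in 146 and farther in 974 of the falls, so it draws the mean away from the control. Cre07g349200 was higher in Mix, at 46.8 ± 17.7 CPM, than in Ce (1.48 ± 0.69), Tm (26.3 ± 8.03) or Y (7.96 ± 2.22), a log2 difference from their mean of 2.79 ± 0.20 (edgeR adjusted p = 2.05e-10). Cre13g603550, which fell in every metal, lay above their mean in Mix at 9.84 ± 4.95 CPM (2.44 ± 0.27, edgeR adjusted p = 1.62e-07). Below the mean were Cre09g410750, at 0.600 ± 0.284 CPM in Mix, 24.6 ± 6.90 in Ce, 0.731 ± 0.295 in Tm and 1.69 ± 0.57 in Y (-2.40 ± 0.34, edgeR adjusted p = 2.78e-06), and Cre12g495250, at 0.268 ± 0.1002 in Mix, 3.81 ± 0.61 in Ce, 0.665 ± 0.316 in Tm and 0.999 ± 0.206 in Y (-2.33 ± 0.32, edgeR adjusted p = 2.24e-06). The share of genes higher in Mix, 46.8%, was 26.9% with library totals alone and 64.2% with control library 1 as the scaling reference. In the larger groups chosen by the metals alone (2540 and 2854 genes), which leave Mix out of the choice and so favour a smaller change in it, 1087 rises were nearer and 333 farther, and under 4 other scalings the closest counts were 748 and 536 among rises and 624 and 261 among falls.

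Against the sum of the single effects on the log2 scale, Mix departed in 9129 genes, 4377 higher and 4752 lower. Among the genes higher in all 3 metals the median sum was 4.11 and the median of Mix 1.095, with Mix below the sum in 2538 genes and above it in 0 by edgeR. Among those lower in all 3 the median sum was -5.10 and that of Mix -1.51, with Mix nearer the control in 2842 and farther in 0. The sum predicts under 1 count per Mix library in 612 of these falling genes, where Mix could not have reached it. Among the other 2242 Mix was nearer the control in 2233, with medians of -4.41 for the sum and -1.29 for Mix. Both groups of genes were chosen by the same 3 effects that the sum adds. A Mix that resembles any 1 metal then lies nearer the control than the sum. These counts were thus close to fixed beforehand and say little about interactions. The largest departures upward by the naming rule were those of Cre13g603550 (15.83 ± 0.70, edgeR adjusted p = 3.11e-17) and Cre01g044450 (12.65 ± 1.00, edgeR adjusted p = 3.86e-12), which fell in each metal. For these the sum predicts 0.00312 and 0.000647 counts per Mix library, so a departure was fixed beforehand and its size has no meaning of its own. Downward they were Cre03g185750 (-12.05 ± 0.53, edgeR adjusted p = 2.54e-17) and Cre12g524200 (-11.50 ± 0.44, edgeR adjusted p = 1.14e-18), which rose in each metal and for which the sum predicts about 350220 and 1395600 counts per Mix library, levels so high that these sizes too say little. With library totals alone, 32.2% of the departures were upward in place of 47.9%.

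**Figure D5:**
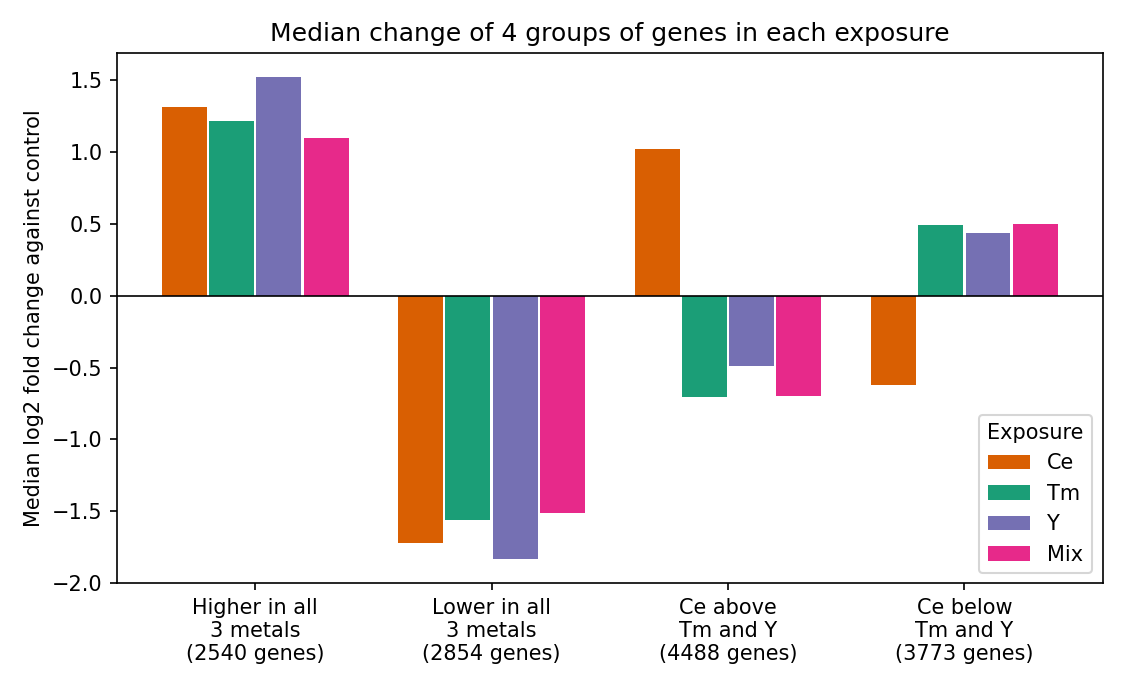
Median log2 fold change against control in Ce, Tm, Y and Mix for 4 groups of genes: those called higher (2540) or lower (2854) in all 3 metals, and those in which Ce was called above (4488) or below (3773) both Tm and Y. The bars are medians over genes without error bars; the common groups were chosen by Ce, Tm and Y without Mix, which favours a smaller median in Mix, and Mix takes the side of Tm and Y where Ce differs.

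Mix was also set against each metal alone, a comparison chosen after the data had been seen. It differed from Tm in 150 genes, 25 higher and 125 lower, with 98.1% of the genes within 2-fold and 1227 at an unadjusted p under 0.05. It differed from Y in 4551 genes (2091 higher, 2460 lower) and from Ce in 10079 (4339 higher, 5740 lower). In the 4488 genes with Ce above Tm and Y, Mix was called below Ce in 4341 and different from Tm in 28, and in the 3773 with Ce below both it was called above Ce in 3545 and different from Tm in 72. Lower in Mix than in Tm were g16355, at 0.516 ± 0.276 against 2.71 ± 1.07 CPM (log2 difference -2.37 ± 0.33, edgeR adjusted p = 3.98e-05), and g12807, at 0.735 ± 0.223 against 3.25 ± 0.47 CPM (-2.16 ± 0.25, edgeR adjusted p = 3.17e-06). Higher were Cre02g112266, at 5.56 ± 1.24 against 2.26 ± 0.72 CPM (1.32 ± 0.27, edgeR adjusted p = 0.00602), and g1873, at 1.01 ± 0.30 against 0.363 ± 0.274 CPM (1.51 ± 0.36, edgeR adjusted p = 0.0293). The call of g1873 was lost in 8 of 27 alternatives, 1 of them only by the threshold of 0.01; its adjusted p ran from 0.00555 to 0.112 and its log2 difference from 1.33 to 1.94. Against Ce, Cre07g349200 (4.98 ± 0.32) and Cre07g336600 (4.31 ± 0.38) were higher in Mix, and Cre06g285050 (-5.36 ± 0.51) and Cre09g410750 (-5.35 ± 0.35) lower. Against Y, g2197 (3.07 ± 0.26) and g11545 (2.94 ± 0.31) were higher in Mix, and Cre17g702950 (-2.49 ± 0.28) and Cre01g003850 (-2.48 ± 0.32) lower. The number of calls between Mix and Tm was 288 (82 higher, 206 lower) with the replicate number as a block, which pairs these libraries, and it ran from 89 (without Tm library 1) to 195 (88 higher, 107 lower, without Mix library 1), with 94, 90 and 95 without Tm library 3, Mix library 3 and Mix library 4. With control library 1 as the scaling reference, the share of genes higher in Mix was 33.8% against Tm, 67.4% against Y and 51.5% against Ce, in place of 16.7%, 45.9% and 43.1%, and with library totals alone it was 23.9% against Ce.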

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

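Of the tests reported in this part, those of equal depth for Ce, the share of abundant transcripts, equal background, libraries of the same number, the axis of the controls and exchanged labels were chosen after the results they bear on had been seen. In 5 of 180 groups of 5 libraries the highest or lowest value stood apart from the other 4 by more than 0.71 of the group's range, where chance alone gives about 9. Tm library 4 scored -53.8 on the second principal component, against -38.8 to -34.9 in the other Tm libraries. Control library 1 had 0.316 CPM of Cre16g6922001 (others 0.0791 to 0.125) and 0.790 CPM of Cre06g285050 (others 0 to 0.0875). Mix library 2 had 0.103 CPM of Cre01g044450 (others 0.229 to 0.260), and Mix library 5 had 20.8 CPM of Cre17g697750 (others 32.3 to 36.1).

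The Ce libraries stood apart from those of Tm, Y and Mix. A difference in depth and a few abundant transcripts that take the reads are argued against, since 9188 genes were called between Ce and Tm at equal depth, against 9796, and the 20 most abundant transcripts held 10.9% of the counts in Ce and 12.2% in Tm, which changes the share left to the others by a factor of only 1.02. An equal amount of background on each gene would add the same CPM everywhere and is argued against, since the median gain of Ce over Tm, in CPM of unscaled library totals, was 8.75 times as large in genes at 1 to 3 CPM in Tm as in those at 0.1 to 0.3 CPM. Other low-level background reads cannot be told apart as a source of rises. They would leave the most abundant 3199 genes alone, of which 35.0% differed 2-fold, but only 18.3% with library totals alone. More transcripts were detected in Ce than in Tm at equal depth (14903 against 14404), as background would give. It adds reads and removes none, yet with library totals alone 7.16% of these abundant genes were at least 2-fold lower in Ce. A further 11.1% were at least 2-fold higher. These falls argue against background as the whole account of the abundant genes. A response to Ce itself stays open as a hypothesis, and the labels give no culture, day or lane per library to test.

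The control libraries spread more than the exposed ones, with a coefficient of biological variation of 32.1% against 9.95% to 17.2%. A difference in depth is argued against, since the value was 31.1% at equal depth (16.3% in Mix), and a single aberrant library does not account for all of it, since the lowest value with 1 control left out was 22.5% (without control 1). A condition shared by libraries of the same number may contribute: control deviations correlated with those of the libraries of their number in the 4 exposures together (mean r across genes 0.109, exact one-sided permutation p = 0.00833, the smallest that 120 orders can give), through Tm and Mix (0.214) and not through Ce and Y (0.00478). The state that separates Ce from Tm may also vary among the controls, because their main axis, 69.2% of their variance, correlated across genes with the Ce minus Tm difference at an absolute r of 0.661. On that axis the controls scored from -63.1 (control 4) to 71.4 (control 1) the Ce libraries from 120.3 to 129, Tm from 16.1 to 38.4 and Y from 48.0 to 57.3, so Tm and Y lay within the control range, and the main axis of the Mix libraries correlated with the same difference at 0.451.

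The Mix libraries lay close to the Tm libraries, with 150 genes called between them (288 with the replicate number as a block). Mix 1 and Tm 4 were slightly nearer the centre of the other group (0.412 against 0.441, and 0.430 against 0.432, root mean square in log2 CPM), but labels exchanged between a Mix and a Tm library are argued against, since exchanging these back left 1 gene called. RNA or cells pooled from the 3 single exposures would give Ce about as much weight as Tm, yet the highest weight of Ce that rebuilt a Mix library was 8.998%, and that of Tm averaged 94.2 ± 4.59% (SD, n = 5). That Tm sets most of the response to the mixture stays a hypothesis that these values allow, and Tm and Mix samples handled together under the same numbers stay open as well.

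Chance as the origin of the counts was examined with 100 splits of the libraries for each of 14 counts. In 13 of them the real split alone (1 of 100) called as many genes. This argues against chance for any difference between the groups and for comparisons of single groups that are not paired by number. A share of 1 in 100 is the smallest that these splits can give. They cannot tell an exposure from a culture, day or lane that the libraries of a group share. The real count and the highest of the other splits were 12292 and 3030 for any difference between the groups, 10376 and 8602 for Ce against control, 8938 and 6041 for Tm, 9292 and 6340 for Y, 8754 and 5779 for Mix, and 9291 and 2785 for the mean of the metals. They were 9796 and 4931 for Ce against Tm, 9435 and 3523 for Ce against Y, 2659 and 2 for Tm against Y, 9129 and 2897 for Mix against the sum, 10079 and 6155 for Mix against Ce, 150 and 12 for Mix against Tm, and 4551 and 976 for Mix against Y. For Mix against the mean of the metals 2 of 100 splits called as many. The other one, with 7544 genes against 6904, put Ce libraries 1 to 4 and Tm library 4 in the place of Mix. It thus followed the separation of Ce. Such splits exchange the distinct Ce libraries with those of other groups, which can by itself lower the count. Therefore they cannot decide on chance for Mix against the mean. The same limit holds for Mix against the sum and for the mean of the metals against control. Among the 16 splits that part all same-numbered pairs, the highest other count was 3083 for Ce against Y and 0 for Mix against Tm by edgeR, with and without the block for the latter.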

How the results depend on the processing

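No named change reversed. The majority direction of the calls did: without the damaged genes it was 4956 higher and 3865 lower for Mix against control, 4661 and 5015 for Ce against Tm and 2147 and 933 for Tm against Y. This came with the TMM reference and not with the genes, since with the reference kept the counts were 3936 and 4796, 5397 and 4357, and 1245 and 1400. Library totals alone, the damaged genes left out, with and without the reference kept, counts summed per ID, a spread per group, equal depth and controls 1 and 4 together were settings chosen after the data had been seen, as were the comparisons of Mix with each metal. Of 243 counts under 18 alternatives, 222 stayed within 1.5 times the reported count and 21 did not. With an adjusted p under 0.01, 1243 genes were called for Tm against Y, 72 for Mix against Tm and 2803 for Mix against Y. With a 2-fold change required as well as an adjusted p under 0.05, which can only remove calls, there were 6766 for Ce, 5390 for Tm, 6006 for Y and 5220 for Mix against control, 5791 for Ce against Tm, 5145 for Ce against Y, 499 for Tm against Y, 1211 for Mix against the mean of the metals, 5151 for that mean against control, 6152 for Mix against Ce, 64 for Mix against Tm and 1126 for Mix against Y. Mix against Tm gave 288 calls with the replicate block, 229 with DESeq2, 241 with 1 surrogate variable and 268 with voom and a spread per group, and Tm against Y gave 4536 with only these groups in the fit and 4621 with voom and a spread per group; the cause was not tested. The replicate block changed no other count by over 1.5 times, with 9772 for Ce against Y and 3518 for Tm against Y.

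With each library left out in turn, counts ran from 10101 to 10758 for Ce, 8692 to 9036 for Tm, 9138 to 9456 for Y and 8592 to 8885 for Mix against control, 9050 to 9767 for the mean of the metals, 9479 to 9702 for Ce against Tm, 9039 to 9260 for Ce against Y, 2365 to 2904 for Tm against Y, 5335 to 6868 for Mix against the mean, 8811 to 9751 for Mix against the sum, 9567 to 9976 for Mix against Ce, 4149 to 4995 for Mix against Y and 12224 to 12422 for any difference. Leaving out 1 library also turned the majority direction, for example to 1730 higher and 635 lower for Tm against Y without Tm 4. Without Mix 4 it was 3682 and 1653 for Mix against the mean and 2833 and 1316 for Mix against Y. Without control 2 it was 4767 and 4142 for Tm against control. The turn was not particular to 1 library, since leaving out any Tm or Y library gave 70.7% to 73.3% higher for Tm against Y. With all libraries kept and control library 1 as the scaling reference this share was 70.4%. A change of reference may therefore lie behind these turns, but the reference of each of these fits was not examined. For Mix against Tm the range was 89 to 195, with 89 without Tm 1, 94 without Tm 3, 90 without Mix 3 and 95 without Mix 4. Without controls 1 and 4 together, the counts against control were 10600, 8890, 9351 and 8669 for Ce, Tm, Y and Mix. Of 1566 values of named IDs 1558 kept their direction and call, and the 8 lost calls were all of g1873 in Mix against Tm. The gene lists and their alternatives were not run because 0 members matched. At about 12921000 counts per library, 8337 of 12040 tested genes were called for Tm against control, in place of 8938 of 12796.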

Other observations

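The tests of detection and of the mixture in separate libraries were chosen after the data had been seen. The mean number of transcripts detected was highest in Ce. With every library thinned to about 12921000 counts, 14903 ± 39.2 transcripts had at least 1 count in Ce, against 14434 ± 184.5 in the controls, 14404 ± 30.4 in Tm, 14544 ± 10.2 in Y and 14354 ± 34.8 in Mix (SD, n = 5). All 5 Ce libraries lay above all libraries of each other group (two-sided exact permutation p = 0.00794 against the control, Tm and Mix, the smallest that 5 against 5 can give, and 0.0106 after Benjamini-Hochberg adjustment over 4 comparisons). Against Y, with which the Ce libraries are paired by number, the exact sign-flip p was 0.0625. That is the smallest that 5 pairs can give, so that test could not pass 0.05. With the numbers ignored the exact permutation p was 0.00794. Ce and Tm missed the rule for pairs only narrowly (lowest correlation 0.0826, against 0.1). If they are paired, a sign-flip test could not pass 0.05 for them either.

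The response in Mix was also measured with direction and size taken from different libraries. Libraries 1 and 2 gave 924 genes at least 2-fold higher and 1363 at least 2-fold lower in all 4 exposures, a choice that favours none of them. In libraries 3 to 5, Mix lay nearer the control than the mean of the other 3 exposures in 76.4% of the rises and 78.1% of the falls, with medians of 1.80 against 2.12 and -2.14 against -2.42 (log2). The same shares were 58.3% and 72.3% for Tm, 53.2% and 47.2% for Ce, and 8.98% and 18.3% for Y.

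Fold changes were similar in neighbouring genes. Over 5559 pairs of adjacent tested genes in the order of the reference assembly, the log2 fold changes of Y against control correlated at r = 0.192, while the highest of 1000 shuffled orders gave 0.0411 (across genes, which are not independent replicates). The values were 0.172 for Ce, 0.208 for Tm and 0.211 for Mix, and for Y r fell to 0.0596 for genes 2 steps apart, still above that value, and to 0.0275, below it, for genes 5 steps apart. Position in the genome may therefore carry part of the response over a few genes; reads of overlapping neighbours that were counted for both would give the same pattern, and this stays open because the use of strand in counting is not given in the sources used here.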
